A study of Homo sapiens with 24 samples.

How the data were processed

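The series holds 24 samples of the H9 line of human embryonic stem cells and of cells derived from it. RNA was sequenced from 4 libraries of asynchronous cells: 2 of undifferentiated cells (ES cells) and 2 of cells labelled PAX6, made by treating undifferentiated cells with retinoic acid for 5 days. The cell type field of the PAX6 RNA samples names the undifferentiated line, against their titles and sources, which were followed. The labels write the dose as 10 mM, a figure that was not checked. Per the labels' protocols, replicate 1 of each condition came from a stock kept in mTeSR-1 medium and replicate 2 from a stock kept in E8 medium, and libraries of one condition were treated as biological replicates. The libraries were made from total RNA with a TruSeq kit and sequenced as read pairs. No strand information is stated, so reads of a gene and of a gene on the opposite strand of the same place cannot be told apart. The other 20 samples, chromatin immunoprecipitations for H3K4me3 and H3K27me3 and their inputs in sorted cell cycle phases, were not analysed here.

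The RNA values come from 1 table of 31017 gene models with coordinates on GRCh37 (hg19), the builds named in the submitters' processing notes. Those notes name CASAVA 1.6 and CASAVA 1.8, Bowtie 0.12.8 and TopHat2 2.0.8b without saying which step each did. The counting tool and the annotation release are not given in the sources used here. Per the file headers, the deposited values are log2 RPKM, reads scaled to gene model length and to library size, with 1 value for ES cells and 1 for PAX6 cells. The values themselves show how the authors combined the libraries: 6531 genes share a single difference between the columns, -0.36 log2, and the next differences lie at steps of 1, 2, 3 and more reads in 1 of 2 libraries. Each deposited value therefore is the authors' mean of the log2 values of 2 libraries, with 0.9 reads entered in place of 0 reads. 39 gene models had no values in their rows and were left out, which leaves 30978. In 9964 rows the gene ID belongs to another, overlapping gene, so symbols and coordinates were used and IDs were not.

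Sequencing depth was recovered from the genes at 0 reads that have a single exon, whose length is their span (690 genes). The geometric mean was 56718139 reads per ES library and 72600797 per PAX6 library, a ratio of 1.28. Among genes with reads in 1 PAX6 library only, 545 had 1 read, 543 had 2, 147 had 3 and 148 had 4. Values of 2 reads are almost as frequent as values of 1 read, as when both mates of a pair are counted. Bounds from read numbers therefore cover counting error only, and reads are not independent. For genes low in 1 condition, the number of reads was solved from the depth and from a whole-number model length of at least 200 bases, trying totals of up to 12 reads and reporting totals of up to 3. A gene at 0 reads in both libraries of a condition has its fold given as a lower bound, against 3 counts per library. In ES cells 3 reads on 1 kilobase come to 0.0529 RPKM, and in PAX6 cells to 0.0413 RPKM.

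The planned analysis was a moderated linear model per gene on values per library, a competitive set test on fixed gene lists and a comparison of the culture media. With 1 deposited value per condition none of these could be run, and the values are given as the authors'. No p-value, standard deviation or n is attached to them, and the differences have no replicate check. Genes with a mean of the 2 RPKM values of at least 1 were kept, as planned (12080 genes, 39.0% of those with values). A gene is called higher or lower where the values differ by at least 2-fold. That size had been listed beforehand as an alternative, and became the rule only after the table was seen to hold 1 value per condition and the values had been looked at in outline. The plan for a test added 1 to each RPKM value before taking logs. The deposited log2 values were used as they stand instead, and the planned pseudocount of 1 is among the alternatives.

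Before the data were examined, 34 gene lists were fixed (815 entries, of which 2 are not in the table). They cover pluripotency, nodal and activin targets, the retinoic acid response, HOX paralogues 1 to 5, 6 to 8 and 9 to 13, neural progenitors, neurons, neural crest and placode, mesendoderm and mesoderm, endoderm, trophoblast and amnion, surface ectoderm, mesenchyme and fibroblasts, endothelium, blood and heart, adhesion, G1/S and G2/M genes, CDK inhibitors and p53 targets, polycomb complexes, H3K4 methyltransferase complexes, H3K4 and H3K27 demethylases, DNA methylation, BMP, WNT and FGF targets, the NOTCH pathway, sterol and fatty acid synthesis, glycolysis and hypoxia, the ATF4 and unfolded protein stress response, cytosolic ribosomal proteins, oxidative phosphorylation and families of developmental transcription factors. For a list with at least 5 members past the filter, the median difference is given with its percentile among 10000 random lists of the same size, matched on decile of mean expression. The percentile describes these values and is not a test between conditions. Random lists share the shift of all genes, so the percentile is relative to it.

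Genes were named by a rule fixed beforehand: PAX6, POU5F1, NANOG and SOX2; the 10 largest differences in each direction among genes with a mean of at least 5 RPKM and a symbol in the reference gene tables; and up to 4 called members of each list with the largest differences, or the most abundant member where none was called. Requirements of the rule on adjusted p-values and on separate libraries could not be applied. The rule names 103 genes, some of which are not reported here. Other list members printed here were chosen after their values were seen. Of the 12080 genes past the filter, 10766 have a symbol in the reference tables.

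An attempt to recover the spread between libraries from the product of their reads was indecisive and was not used. The recovery of depth and low reads was tested on simulated data with 30978 genes made like the comparison of PAX6 with ES cells. Of 19 simulated genes at 0 reads, 78.9% were called 0, and all 15 genes called 0 were truly at 0. All 21 reported totals of at most 3 reads were right. The list percentile was tested on a separate set of simulated genes with independent, normally distributed differences. Unlike the deposited values, these had no trend with expression, so the outcome may not carry over to them. Among 20 lists of 20 genes shifted by 1 log2, 17 lay above the 97.5th percentile, and 1 of 20 unshifted lists lay outside the central range. The alternatives tried were pseudocounts of 0.1 and 1, quantile normalization, no filter, a filter of at least 5 RPKM in either condition and, chosen after seeing the data, centring on the median gene, genes at 0 reads placed at their bound, gene models without overlap, and a 4-fold rule. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.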

Results

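Gene expression was measured by RNA sequencing in asynchronous H9 cells, an established human embryonic stem cell line, before differentiation (ES cells) and after 5 days of retinoic acid (PAX6 cells). The sample titles and sources describe the treated cells as PAX6 cells or positive for PAX6, a transcription factor of the early neural plate and eye. Their cell type field instead names the undifferentiated line, and titles and sources were followed. Each condition had 2 libraries, with a geometric mean of 56718139 reads per library in ES cells and 72600797 in PAX6 cells, as recovered from the values. The deposited table gives 1 value per condition, the authors' mean log2 RPKM, so no difference has a replicate check. Coordinates are those of GRCh37.

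The comparison asks which transcripts differ between undifferentiated cells and cells treated with retinoic acid. Transcripts of the core pluripotency factors were lower in PAX6 cells: POU5F1 stood at 178 RPKM in ES cells and 11.2 in PAX6 cells, and NANOG at 27.4 and 0.666. HOX genes of paralogue groups 1 to 5, which pattern the hindbrain and anterior trunk, were close to 0 reads in ES cells and reached 57.5 RPKM for HOXB1 and 15.9 for HOXB2 in PAX6 cells. Of the 24 retinoic acid response genes 14 were higher, among them CYP26A1, whose product degrades retinoic acid, at 3.52 and 129 RPKM. PAX6 itself (chromosome 11, 31806340 to 31839509, minus strand) was at 0.0367 RPKM in ES cells and 2.15 in PAX6 cells. Simple epithelial keratins and BMP targets were also higher, while most cell cycle genes lay within 2-fold.

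Of 12080 genes past the filter, 1160 were at least 2-fold higher in PAX6 cells, 643 were at least 2-fold lower and 10277 lay within 2-fold. Higher genes made up 64.3% of the 1803 that differed. The median gene was 0.12 log2 higher in PAX6 cells, and 385 genes at 50 RPKM or more in both conditions had a median of 0.03. Quantile normalization gave 837 higher and 848 lower genes (49.7% higher) and moved the median gene by -0.17 log2, while centring on the median gene gave 953 and 769 (55.3%). The balance of directions therefore depends on the scaling chosen. Quantile normalization forces the distributions to match and centring removes the positive median, so neither shows which scaling is right. With 1 added to each RPKM value, as planned for a test, 641 genes were higher and 420 lower. At the 4-fold size 378 genes were higher and 238 lower. Across genes past the filter the columns had a Pearson r of 0.787, where genes are not independent replicates.

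**Figure D1:**
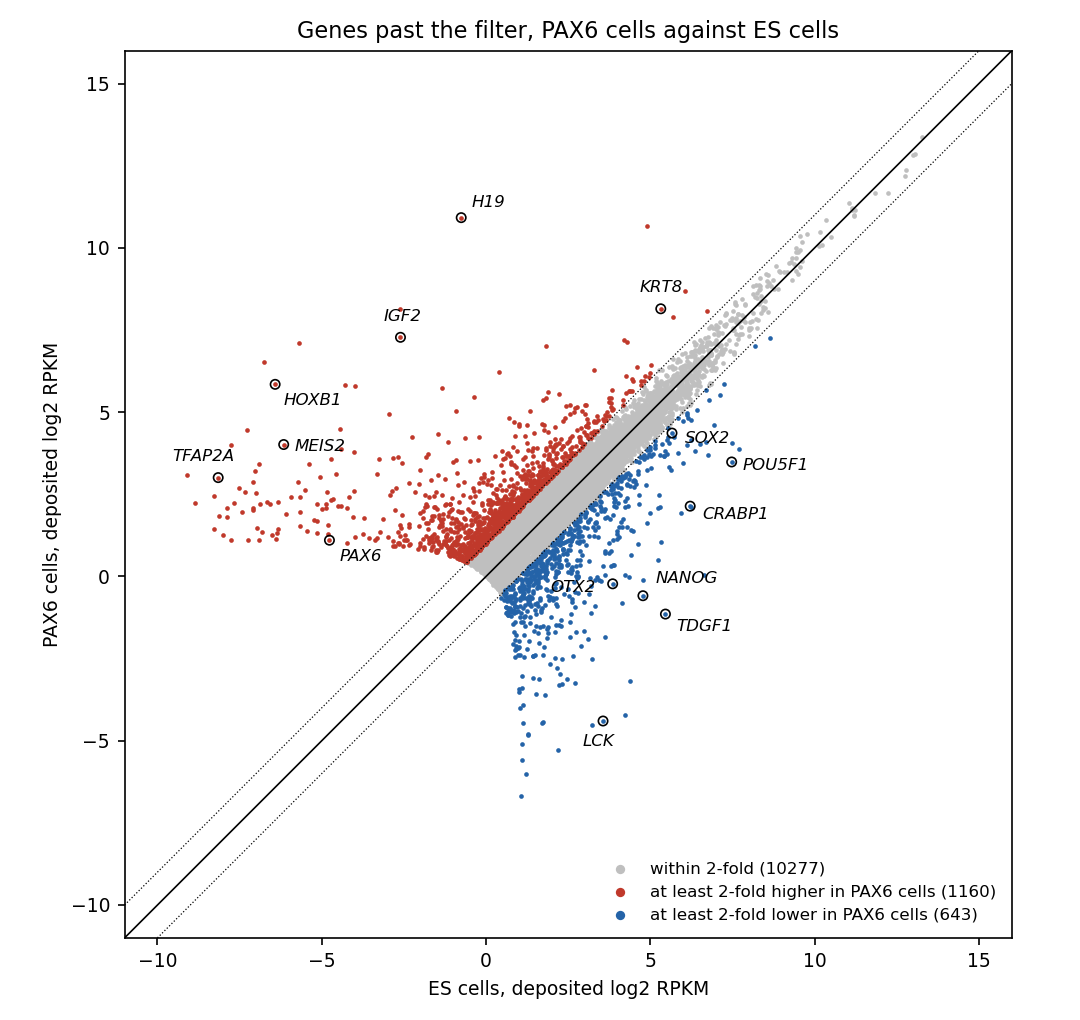
Deposited log2 RPKM of 12080 genes in ES cells (x axis) and PAX6 cells (y axis), 1 point per gene, with 1160 genes at least 2-fold higher in red, 643 at least 2-fold lower in blue and the rest in grey; the solid line marks equal values and the dotted lines 2-fold. H19 and HOXB1 lie far above the line and LCK and TDGF1 far below it.

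Among genes with a mean of at least 5 RPKM, the largest differences upward included several genes of the HOX clusters. HOTAIRM1, a noncoding RNA of the HOXA cluster whose model overlaps its neighbours and can share their reads, was at 0.0193 RPKM in ES cells and 138 in PAX6 cells. HOXB1 (chromosome 17, 46606550 to 46608359, minus strand) and HOXB2 had 0 reads in ES cells and were at least 1477-fold and at least 1031-fold higher. H19, an imprinted noncoding RNA (chromosome 11, 2016406 to 2022700, minus strand), stood at 0.592 RPKM in ES cells and 1938 in PAX6 cells. Its neighbour IGF2, which encodes a fetal growth factor, stood at 0.164 and 155, and the readthrough model INS-IGF2, which overlaps IGF2 and shares its reads, at 0.0633 and 55.8. DLX5, a homeobox gene of placode and neural crest, had 0 reads in ES cells and was at least 387-fold higher. MEIS2, a cofactor of HOX proteins, was at 0.014 and 16.2 RPKM, and ANKRD1, a muscle ankyrin repeat gene, at 0.0463 and 22.4.

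Under the same limit, the 10 largest differences downward had the SRC-family kinase gene LCK first, at 11.8 RPKM in ES cells and 0.0474 in PAX6 cells. TDGF1, which encodes a coreceptor of NODAL (chromosome 3, 46616045 to 46668033, plus strand), was at 44 and 0.452. POLR3G, a subunit of RNA polymerase III, was at 37.8 and 1.42, and LECT1, which encodes chondromodulin, at 20.5 and 0.982. PMAIP1, a proapoptotic member of the BCL2 family, was at 40.4 and 2.05. The head and forebrain factor OTX2 was at 14.5 and 0.856, and CRABP1, a cellular retinoic acid binding protein gene, at 74.2 and 4.4. POU5F1B, a near-identical copy of POU5F1 that can take its reads, was at 74.8 and 4.34. A gene model named MIR4454 in the table spans 27639173 to 27656174 on chromosome 11 and overlaps BDNF-AS1. Its 99.1 and 1.02 RPKM are reads over that span and not a measure of a mature microRNA. NANOG completed the 10.

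In the pluripotency list 20 of 27 genes past the filter were at least 2-fold lower and 0 were higher. Of the 20 genes 6 were below 1 RPKM in PAX6 cells, so the filter fixed their direction. The median was -2.13 log2, below all 10000 random lists (percentile 0). FOXD3 was at 2.35 RPKM in ES cells and 0.0155 in PAX6 cells, and PRDM14, a PR-domain regulator of pluripotency, at 4.48 and 0.146. The DNA methyltransferase gene DNMT3B was at 69.7 and 15.9, and SOX2, which neural progenitors also express, at 50.5 and 20.6. LIN28A, which encodes an RNA-binding protein that blocks let-7 maturation, was at 232 and 237, and SALL4 at 13 and 18.1, both within 2-fold. Targets of nodal and activin signalling went both ways (2 higher and 2 lower of 6 past the filter, from 11, median 0.10 or, after quantile normalization, -0.05, percentile 44.1). TDGF1 and FOXH1 (8.3 and 1.94) were lower, whereas LEFTY2, which encodes a secreted inhibitor of nodal, was at 1.14 and 9.1. LEFTY1, at 1.04 and 2.74, was within 2-fold when 1 RPKM was added.

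The retinoic acid list had 17 of 24 genes past the filter, 14 higher and 1 lower, with a median of 3.34 log2 (percentile 100). Of the 14 genes 7 were below 1 RPKM in ES cells. The receptor gene RARB was at 0.0382 RPKM in ES cells and 11.9 in PAX6 cells, and the HOX cofactor gene MEIS1 and the nuclear receptor gene NR2F2 were at 0.00622 and 5.95 and at 0.0106 and 4.62. CRABP2, which delivers retinoic acid to its receptors in the nucleus, was at 30.1 and 1622. CRABP1 was the gene that was lower.

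Of 15 genes of HOX paralogues 1 to 5, 13 passed the filter, with a median of 10.25 log2 (percentile 100), or 9.38 with 8 genes that had 0 ES reads placed at their bound and 2.69 with 1 RPKM added. The 9.38 is the value of HOXC4. Its ES reads, like those of HOXA3 and HOXB5, could not be solved, so these genes were not placed at a bound. A gene as close to 0 in ES cells as these HOX genes passes only with about 2 RPKM or more in PAX6 cells, so the filter fixes its direction. The same holds for any gene below 1 RPKM in 1 condition: 498 of the 1160 higher genes were below it in ES cells and 270 of the 643 lower genes in PAX6 cells. HOXB3 was at least 1403-fold higher. Of paralogues 6 to 8, 1 of 8 passed the filter, HOXB6, at 2.41 RPKM and at least 186-fold higher. None of the 16 genes of paralogues 9 to 13 passed. In ES cells all 39 HOX genes were at 0.0152 RPKM or less, below the level of 3 reads on 1 kilobase. Across the 39 genes the PAX6 value was lower at higher paralogue number (Spearman rho across genes -0.878). Within the HOXA and HOXB clusters rho was -0.982 and -0.988, and in HOXC and HOXD it was -0.733 and -0.65. Neighbouring HOX models overlap on these clusters, so their values are not independent. Several genes at high paralogue numbers, among them HOXA11, HOXC10 and HOXD10, had 0 reads in every library. Their values, and so their ranks among each other, reflect model length and not expression.

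**Figure D2:**
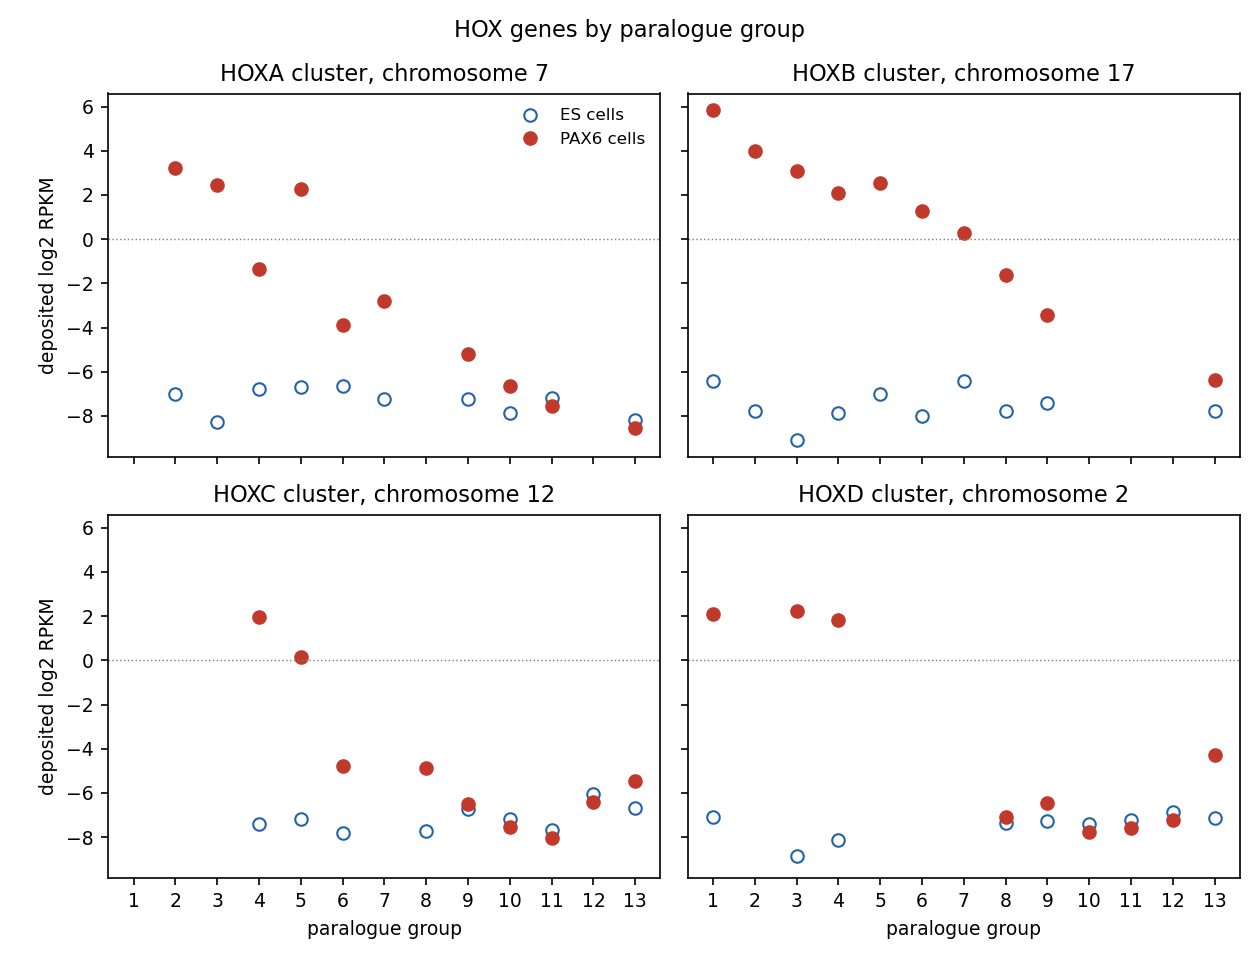
Deposited log2 RPKM (y axis) of 38 HOX genes by paralogue group (x axis) in the 4 clusters, with open circles for ES cells and filled circles for PAX6 cells; the dotted line is 1 RPKM, and 1 of the 39 genes is not plotted. PAX6 values are highest in the first groups of each cluster, with a rho over all genes of a cluster of -0.982 in HOXA and -0.988 in HOXB.

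Of 30 neural progenitor genes 12 passed the filter and went both ways, with 4 higher and 5 lower (median 0.42, percentile 94.9). The filter fixed the direction of 3 of the 4, below 1 RPKM in ES cells, and of 3 of the 5, below 1 RPKM in PAX6 cells. Apart from PAX6 and MEIS2, CDH2, which encodes N-cadherin, was at 6.8 RPKM in ES cells and 35.7 in PAX6 cells. The anterior genes OTX2 and POU3F1 (4.26 and 0.78) were lower. Of 25 neuronal genes 8 passed, and 2 were higher and 3 lower (median -0.34, percentile 1.79): the neurofilament gene NEFM was at 3.37 and 13, the neuronal tubulin gene TUBB3 at 43.7 and 14.2, and the RNA-binding protein gene ELAVL2 at 2.57 and 0.64. In the neural crest and placode list 8 of 22 genes passed, with 4 higher and 1 lower (median 3.62, percentile 100). That median was 1.23 with 1 RPKM added, since the 4 genes that were higher had ES values near 0 and a direction fixed by the filter. TFAP2A, a transcription factor of surface ectoderm and neural crest, was at 0.00351 and 8.04, and the homeobox genes MSX2 and DLX3 were at 0.0221 and 6.21 and at 0.0356 and 2.99.

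In lists for other lineages most members lay below the filter. Of 20 surface ectoderm genes 8 passed and 7 were higher, 2 of these below 1 RPKM in ES cells (median 1.96, percentile 100), with KRT8 at 39.9 and 283, KRT18 at 51.5 and 241 and KRT19 at 18.3 and 146 RPKM. The KRT8 and KRT18 models overlap at their ends. Of 22 trophoblast and amnion genes 5 passed and were higher, but 4 were below 1 RPKM in ES cells, so the filter fixed their direction (median 2.81, percentile 99.98), among them GATA3 at 0.0162 and 5.29, IGFBP3 at 0.285 and 12.3 and KRT7 at 0.859 and 6.01. Of 20 endoderm genes 6 passed and 3 were higher, all below 1 RPKM in ES cells (median 3.56, or 1.10 with 1 RPKM added, percentile 100): GATA6 had 0 ES reads and was at least 250-fold higher, and FOXA1 was at 0.00858 and 4.62. Of 24 mesendoderm and mesoderm genes 3 passed the filter, with MEOX1 higher (0.0124 and 2.7) and the VEGF receptor gene KDR lower (8.54 and 0.266). Of 16 endothelial, blood and heart genes 4 passed, with CDH5 (0.0839 and 2.25) and ACTC1 (2.46 and 9.29) higher and KDR lower. Of 17 mesenchyme and fibroblast genes 6 passed, 3 higher and 1 lower (median 1.01, percentile 99.8), with COL1A2 at 2.29 and 8.15 and the surface glycoprotein gene THY1 at 61.1 and 3.82. That median was below 1 under 4 of the alternatives.

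Of 16 adhesion genes 11 passed, 3 higher and 1 lower (median 0.25, percentile 89.2). CDH6 was at 0.155 and 12.4 RPKM and fibronectin (FN1) at 1.55 and 13.3, while E-cadherin (CDH1) was at 18.4 and 21.8. BMP targets were higher in 8 of 10 cases, 5 of them below 1 RPKM in ES cells (median 3.19, percentile 100), with the HLH inhibitor gene ID4 at 0.861 and 18.8 and ID1 at 9.8 and 77.5. Of 16 WNT targets 5 passed the filter and 3 were higher, 2 of these below 1 RPKM in ES cells (median 1.52, percentile 99.5), namely CDX1, a caudal homeobox gene that also responds to retinoic acid, at 0.0122 and 2.5, TNFRSF19 at 0.0466 and 4.4, and the feedback gene AXIN2 at 1.35 and 3.86. FGF targets were lower in 6 of 14 cases and higher in 1 (median -0.60, percentile 0.01). The feedback inhibitor gene SPRY4 was at 15.9 and 2.61, and the ETS factor genes ETV1 and ETV4 were at 6.15 and 1.14 and at 22.8 and 6.53. NOTCH pathway genes went both ways (2 higher and 3 lower of 8 past the filter, from 16, median 0.04 or, after quantile normalization, -0.21, percentile 25.3), with HES1 at 3.81 and 13.3 and the glycosyltransferase gene LFNG at 3.57 and 1.16. Transcription factors of developmental families passed the filter in 44 of 167 cases, with 15 higher, 12 of these below 1 RPKM in ES cells, and 9 lower (median 0.51, percentile 99.9).

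**Figure D3:**
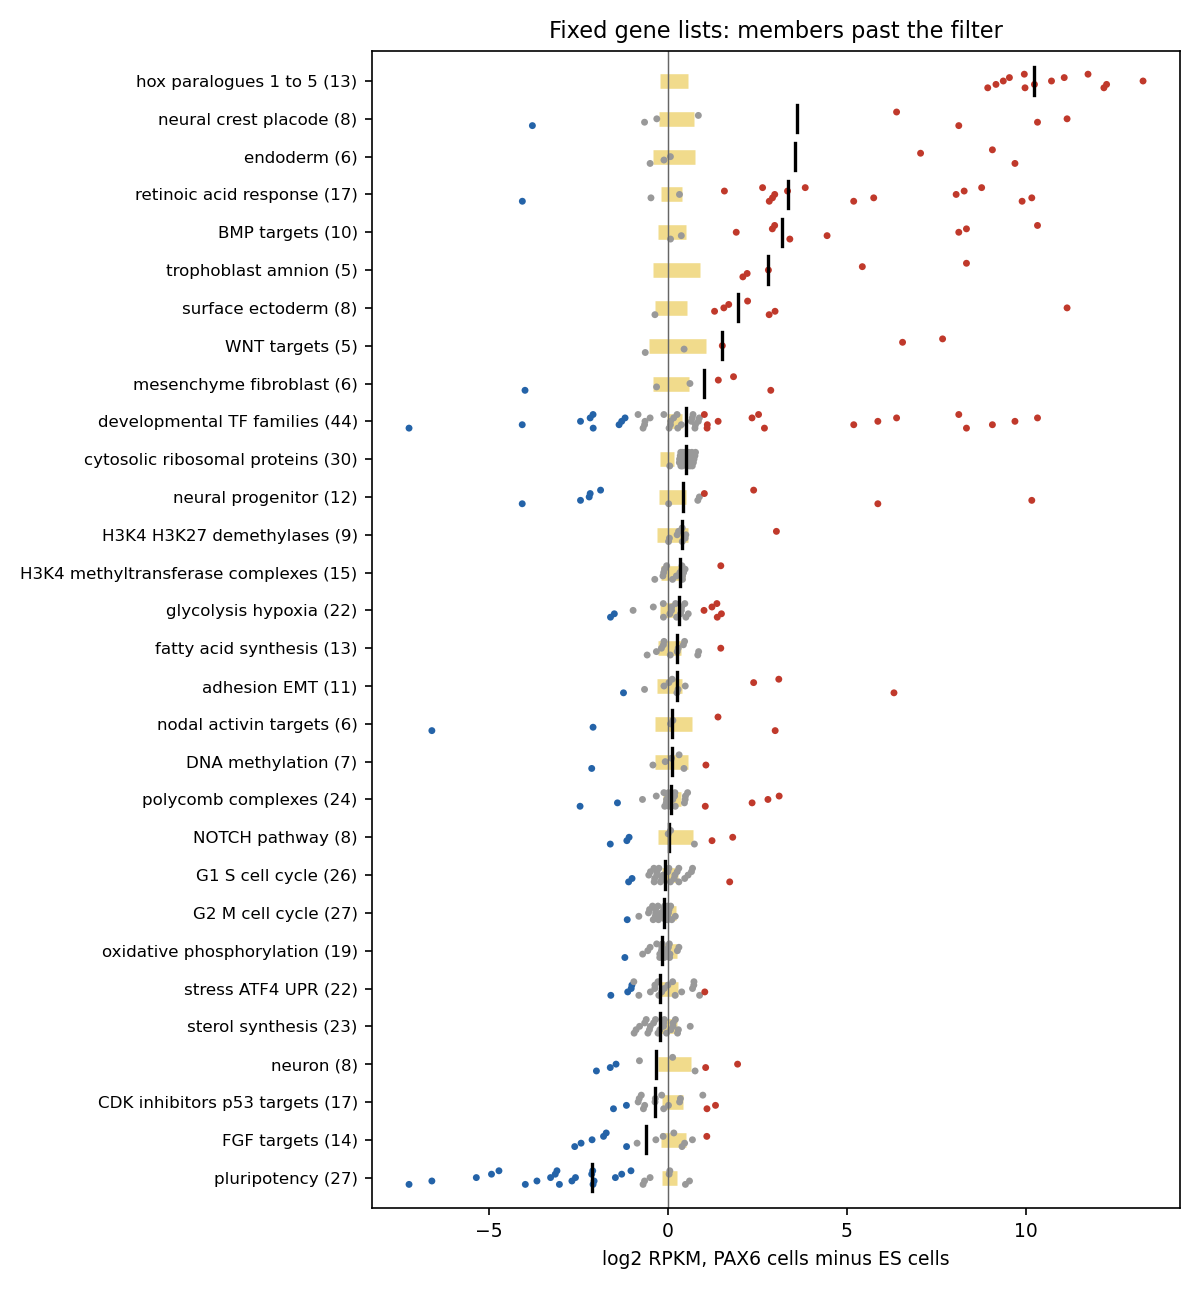
Log2 RPKM of PAX6 cells minus ES cells (x axis) for members past the filter of each list with at least 5 of them (list and number of members on the y axis); points are genes, red at least 2-fold higher and blue at least 2-fold lower, black bars are list medians, and yellow bands hold 95% of the medians of 10000 random lists. HOX paralogues 1 to 5 have the highest median, 10.25, and pluripotency genes the lowest, -2.13.

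Cell cycle genes differed little. Of 26 G1/S genes 1 was higher and 2 lower (median -0.07, percentile 15.8), with the kinase gene CDK6 at 1.54 RPKM in ES cells and 5.1 in PAX6 cells and cyclin E1 (CCNE1) at 11 and 5.5, which was within 2-fold with 0.1 or 1 RPKM added. Of 27 G2/M genes 22 lay below 0 and 5 above 0 (median -0.12, percentile 12.3). Only 1, the checkpoint kinase gene BUB1, was at least 2-fold lower (35.1 and 15.9). CDK inhibitors and p53 targets had a median of -0.36 log2 (percentile 0.11), with 2 of 17 higher and 2 lower, and RRM2B, a p53-induced ribonucleotide reductase subunit, at 15 and 5.19.

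Among chromatin regulators, polycomb genes were higher in 4 of 24 cases and lower in 2 (median 0.08 or, after quantile normalization, -0.05, percentile 43.3). The paralogues PHC1 and PHC2 of the PRC1 complex went opposite ways, PHC1 from 90.6 RPKM in ES cells to 16.5 in PAX6 cells and PHC2 from 2.39 to 16.6. BMI1, which also encodes a PRC1 subunit and whose model overlaps COMMD3, was at 0.924 and 4.71, and the PRC2-associated gene C17orf96 at 0.955 and 8.23. Of 15 genes of H3K4 methyltransferase complexes 1 was higher, NCOA6 (0.878 and 2.44; list median 0.33, percentile 88.6), and it was within 2-fold when 1 RPKM was added. Among 9 demethylases 1 was higher, the H3K27 demethylase gene KDM6B at 0.407 and 3.33 (list median 0.40, percentile 89.5). In the DNA methylation list DNMT3B was lower and UHRF1, which recruits DNMT1, was at 4.01 and 8.35 (1 higher and 1 lower of 7, median 0.10 or, centred, -0.02, percentile 56.2), and UHRF1 was within 2-fold under 3 alternatives.

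In metabolism, 0 of 23 sterol synthesis genes differed by 2-fold (median -0.23, percentile 1.87). Of 13 fatty acid genes 1 was higher, the elongase gene ELOVL6 (14 and 38.8 RPKM; median 0.26, percentile 90.5). Glycolysis and hypoxia genes were higher in 5 of 22 cases and lower in 2 (median 0.29, percentile 99.0), with the glucose transporter gene SLC2A1 at 22 and 61.9, hexokinase 1 (HK1) at 24.8 and 8.76 and aldolase C (ALDOC) at 17 and 5.56. The stress list was lower in 4 of 22 cases and higher in 1 (median -0.22, percentile 1.66), and the lower genes included asparagine synthetase (ASNS, 39.1 and 12.9) and the serine and folate pathway genes PSAT1 (103 and 50.7) and MTHFD2 (31.6 and 14.4). Oxidative phosphorylation genes had 1 of 19 lower, cytochrome c (CYCS, 35 and 15.2; median -0.16, percentile 9.86). Cytosolic ribosomal protein genes all lay within 2-fold, yet 30 of 30 were above 0, with a median of 0.50 log2 (percentile 100). After centring 29 were above 0 (RPL7 was not), and after quantile normalization 26 were, without RPL7, RPL8, RPL19 and RPS2, with a median of 0.29. Reads on mitochondrial gene models made up 4.37% of reads in ES cells and 3.81% in PAX6 cells.

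Limits apply to all of these values. Of the genes past the filter 6226 (51.5%) overlap another gene model and can share its reads, and values below 3 reads depend on the 0.9 reads entered for 0.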

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

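All alternatives were run on the size of the difference, since no test exists; those on centring, bounds, overlap and the 4-fold rule were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per condition, and for that reason leaving out a library, a replicate block, other size factors, other count or linear models, thresholds on p, other set test correlations and the comparison of media were not run. The main count was 1803 genes, 1160 higher and 643 lower. Adding 1 RPKM gave 1061 (641 higher, 420 lower), since it shrinks differences of low genes. With no filter, 24447 genes gave 7042 (4045 and 2997). At 5 RPKM or more in either condition, 6350 genes gave 791 (492 and 299). Genes with no overlapping model (5854) gave 923 (546 and 377), and genes with no overlapping model past the filter (7629) gave 1260 (763 higher, 497 lower). The 4-fold rule gave 616 (378 and 238). A pseudocount of 0.1 (1705), quantile normalization (1685), centring (1722) and bounds for 0 reads (1803) stayed within 1.5 times in number. No named gene changed direction under a pseudocount, quantile normalization, centring or bounds. Of 103 named genes, 12 fell within 2-fold with 1 RPKM added (LEFTY1, INA, PGF, SNAI1, CCND3, CCNE1, BBC3, TP53INP1, NCOA6, UHRF1, NRARP and HERPUD1), 3 after quantile normalization and 3 after centring (TP53INP1, UHRF1 and HERPUD1 in both), and 1 with 0.1 added (CCNE1). Among 33 list medians, that of mesenchyme and fibroblast genes moved below 1 under 4 alternatives, and 4 medians near 0 changed sign: nodal and activin targets (0.10; -0.05 after quantile normalization, -0.02 centred), polycomb genes (0.08; -0.05, -0.04), NOTCH genes (0.04; -0.21, -0.08) and DNA methylation genes (0.10; -0.02 centred). With 1 RPKM added the medians of HOX paralogues 1 to 5 (10.25), neural crest and placode (3.62) and endoderm (3.56) were 2.69, 1.23 and 1.10. Depth limits low genes: at least 18 genes past the filter had 0 reads in both ES libraries and at least 5 had 1 to 3. Reads could not be solved for every low gene.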

Other observations

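Tests of scaling by abundant genes, of spans up to the median ribosomal one, of leftover cells and of library depth were chosen after the result was seen, as were the families of genes described first.

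Of 43 collagen genes 16 passed the filter, and 11 were at least 2-fold higher in PAX6 cells and 0 lower (median 1.6 log2, percentile 100 of matched random lists). COL2A1, the main collagen of cartilage and also of notochord, stood at 0.781 RPKM in ES cells and 44.5 in PAX6 cells, and the basement membrane genes COL4A1 and COL4A2, which lie head to head, at 5.02 and 15.8 and at 4.39 and 15.9. Genes below 1 RPKM in ES cells, whose direction the filter fixes, were 2 of these 11, 6 of the 8 higher semaphorins and plexins, 4 of the 7 higher ephrins and receptors and 5 of the 8 higher genes of the WNT families. Semaphorins and plexins, which guide axons and cell movement, were higher in 8 of 19 cases past the filter, from 28, and lower in 1 (median 0.80, percentile 99.95), with PLXNA2 at 0.0618 and 6.00 and SEMA3C at 0.0384 and 5.00. Ephrins and their receptors were higher in 7 of 16 cases, from 22, and lower in 1 (median 0.78, percentile 99.9), led by EPHB3 (0.222 and 6.00) and EFNB2 (1.93 and 14.1). WNT ligands, frizzled receptors and secreted antagonists were higher in 8 of 14 cases, from 37, and lower in 1 (median 1.26, percentile 100), with SFRP5 at 0.637 and 18.5, FZD4 at 0.837 and 11.6, and SFRP1 the lower one at 81.5 and 14. Of 50 keratin genes 5 passed the filter and 4 were higher, KRT7, KRT8, KRT18 and KRT19, which the surface ectoderm or the trophoblast list also holds. Of 23 claudin genes 10 passed and 4 were higher, 2 of these below 1 RPKM in ES cells (median 0.48, percentile 94.3). Among the 4 was the tight junction gene CLDN4 at 1.38 and 10.6.

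Among the other families tried, ligands and antagonists of the TGF-beta and BMP families were higher in 3 of 9 cases, from 31 (median 0.69, percentile 96.6). Of the 3 genes 2 were below 1 RPKM in ES cells, so the filter fixed their direction: BMP4 at 0.541 and 8.89 RPKM and its antagonist NOG at 0.0745 and 2.46. FGF ligands and receptors had 1 of 8, from 26, higher and 1 lower (median 0.32, percentile 84.8), and KLF and SP factors 2 of 14, from 26, higher and 1 lower (median 0.14, percentile 37.0). Genes named ZNF with a number were higher in 23 of 323 cases, from 477, and lower in 3 (median 0.21, percentile 51.5). Of the 23 genes 10 were below 1 RPKM in ES cells. Of 15 replication-dependent histone genes 5 passed the filter (median -0.75, percentile 1.03). Proteins of the mitochondrial ribosome had a median of -0.17 over 72 genes (percentile 0.12). In a wider list of 76 cytosolic ribosomal protein names the median was 0.41 (percentile 100), 74 were above 0, and RPS26 was the only one at least 2-fold lower, at 69 and 29.9.

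Whether imprinted genes other than H19 and IGF2 differ as a class was asked before their values were seen. Their median over 14 genes was 0.32 log2, inside the range of 95% of random lists, -0.24 to 0.36 (percentile 95.5). By the rule written beforehand, a median inside that range counts against a difference as a class. A bootstrap 95% interval of -0.10 to 0.67, added after the median was seen, reaches past the upper limit. Under that later rule the values leave the question open. Of the 14 genes 9 were above 0, 2 were at least 2-fold higher and 3 lower. DLK1 was at 0.243 and 7.05 RPKM and PEG10 at 12.7 and 27.1, while SNRPN (152 and 58.2), SNURF from the same locus (111 and 41.6) and GRB10 (6.03 and 2.1) were lower.

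Cytosolic ribosomal protein genes were higher by a median of 0.50 log2, from 0.05 to 0.77, and by 0.29 after quantile normalization, when 26 of 30 were above 0. The values argue against scaling of all abundant genes: 373 other nuclear genes at 50 RPKM or more had a median of -0.088 (bootstrap 95% interval -0.129 to -0.0311). A limit at the longest ribosomal span, 48253 bases, kept 334 of these genes (median -0.0897) and decides nothing on short spans. The 104 with spans up to the median ribosomal one, 4933 bases, had a median of -0.0636 (-0.145 to 0.0762). That argues against short spans as the cause. Spans include introns, so the cut cannot decide on an effect of short transcripts, which was not tested. Reads shared with the many processed pseudogenes of these genes were not tested and stay open. A biological difference between the conditions, such as in ribosome production, may also underlie it and was not tested.

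Pluripotency transcripts remained in PAX6 cells at a median of 22.8% of their ES level over 19 genes at 10 RPKM or more in ES cells, and 15 of these kept over 10%. If undifferentiated cells at ES levels were the whole source, all would be left at about the same percent. The median was 22.2 times the percent of the lowest gene, TDGF1 (1.03%), and 9.37 times that of NANOG (2.43%), which argues against it for most of the list. Leftover cells as part of the signal, slow loss of stable transcripts and expression in the treated cells stay open. LIN28B, at 152% of its ES level, was the highest.

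More genes were higher than lower in PAX6 cells. One scaling factor as the whole cause would shift every abundance class alike, but the median of genes at 1 to 5 RPKM (0.24, bootstrap 95% interval 0.22 to 0.26) exceeded that of genes over 50 RPKM (0.00, -0.04 to 0.06) by 0.23 log2. Deeper PAX6 libraries as the cause would leave the directions even among well-covered genes. At 5 RPKM or more in either condition 62.2% of 791 genes were higher (Wilson 95% interval across genes, which are not independent, 58.8% to 65.5%). Over 50 RPKM the directions were about even, with 15 higher and 17 lower (46.9%), against 316 and 191 at 5 to 50 RPKM (62.3%). The outcome thus depends on the abundance class, and a gene can pass the 5 RPKM limit through 1 condition alone. These values therefore do not settle the part of depth. Centring on the median gene gave 55.3% (953 higher, 769 lower) in place of 64.3%. Removing a positive median lowers this share whatever its cause, so centring cannot tell whether 1 factor made part of the excess. Scaling that depends on abundance also stays open, since quantile normalization gave 49.7%, although it forces the distributions to match. Induction of genes silent in ES cells may contribute. Below 1 RPKM in ES cells were 498 of the 1160 higher genes, and below 1 RPKM in PAX6 cells 270 of the 643 lower genes. These shares are about alike, which argues against such genes as the whole source of the excess. Their part in it was not tested further.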
